A study of Homo sapiens with 9 samples.

How the data were processed

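The series holds 9 RNA sequencing libraries of the human B-cell line BJAB, 3 each of the parental line (control), of cells given the long isoform of TACI and of cells given the short isoform. The sample titles speak of stable transfection and the series summary of transduction. Per the labels, polyadenylated RNA came from sorted cells, was extracted with the RNeasy Plus Micro kit and had an integrity number above 8, and libraries were made with Nextera XT, which does not keep the strand. Antisense and overlapping genes therefore cannot be told apart.

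The values are raw counts per gene, as deposited by the authors, without normalization. The notes of the authors name FastQC, STAR 2.4.0h, HTSeq and build hg38, while the columns of the deposited count files are laid out as featureCounts writes them. The annotation release, the strand setting and any filter are not stated. Each library has a count for 57500 Ensembl genes, of which 56898 are in GENCODE release 29, the source of gene types, and 54773 have the same start and end there.

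Total counts per library ran from 40322136 to 50079203. Intervals printed for genes with few counts are exact 95% intervals of the ratio and cover counting error only, since reads without molecular identifiers are not independent molecules. No library was a copy of another: the chi-square per degree of freedom between replicates ran from 2.45 to 18.2. HLA and immunoglobulin genes, the HSPA1A and HSPA1B pair and mitochondrially encoded genes with nuclear copies share reads with near-identical sequences, so their values are uncertain.

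The comparisons, the tests, 22 gene lists and the alternatives were fixed before the data were examined. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 16672 genes, 12806 of them protein-coding. They were scaled with TMM factors and fitted over all 9 libraries with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (6 residual degrees of freedom, common biological coefficient of variation 0.0792). Genes were called at a Benjamini-Hochberg adjusted p under 0.05. CPM values use the TMM factors. Standard errors of log2 fold changes are approximate: the absolute log2 fold change divided by the square root of the F statistic of the same fit. Each list was tested with limma 3.58.1 camera at a preset correlation of 0.01, adjusted over 22 lists and 3 comparisons, and also with an estimated correlation and with fry. Of 66 list results, 54 had the same counts of called members when adjusted over the list alone.

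Genes named in the text follow a rule fixed before the data were examined. It takes, in each comparison, TNFRSF13B, the 8 rises and 8 falls of greatest size among called protein-coding genes with an average log2 CPM of at least 1 and groups that do not overlap, and up to 4 called members of each list by adjusted p. It also takes 6 genes with the same sign and 4 with opposite signs in both lines, and the marker of another cell type with the highest level in a group. Between 60.5 and 71% of genes had groups that do not overlap, against 10% by chance. The rule names 307 results apart from TNFRSF13B; the text prints a part of them, and a part of those that lost their call under an alternative, while counts over alternatives cover all 307. TYROBP, ITGAM, SOD2, TNFSF13 and TNFSF13B fall outside the rule or were picked after their values were seen.

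On simulated counts with 200 changed genes, the same fit found 47.8 to 67.2% of genes changed 1.5-fold, 68.7 to 76.1% at 2-fold and 86.4 to 92.4% at 4-fold, with 15 to 17 false calls among 16672 genes. In the data 8518 to 11474 genes were called per comparison. False calls and shares found depend on how many genes change, so the simulated values do not carry over to the data. With 1 list raised 1.5-fold, camera called it in 2 of 2 tests and called 0 of 64 unchanged ones. Simulated genes were drawn independently, so this does not show how often lists of correlated genes would be called falsely. Alternatives were DESeq2 1.42.0 and its size factors, upper-quartile factors, limma-voom, other filters on low counts, the groups compared alone, the replicate number as a block, minimum sizes of change and each library left out.

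Some choices were made after results were seen. TACI short replicates 2 and 3 hold more of some transcripts than replicate 1, so 124 genes at least 6-fold higher in them than in replicate 1, at 5 CPM or more, were taken as a measure of that level in each library. Genes whose level follows that measure were removed in further alternatives. Of 2 definitions tried, the first took a share above 10% in any library (3301 genes). It takes in genes near 0 CPM and was replaced, once its result was known, by the share in the group where the gene is highest (1929 genes); the closing part gives both. For the level of TNFRSF13B in control replicate 1, 2 selections of comparison genes were tried, and both are given. Figures were drawn with matplotlib 3.10.9.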

Results

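BJAB is an established human B-cell line that the labels assign to Burkitt lymphoma. TACI, encoded by TNFRSF13B, is a receptor of the TNF receptor family on B cells that binds the cytokines BAFF and APRIL, and B cells make a long and a short isoform of it. Polyadenylated RNA was sequenced from 3 libraries of parental BJAB cells (control), 3 libraries of cells given the long isoform (TACI long) and 3 of cells given the short isoform (TACI short), all without stimulation. The sample titles call these cells stably transfected and the series summary calls them transduced. The total count per library lay between 40322136 and 50079203. Between 24307 and 25938 genes had at least 1 count in 7 of the libraries, against 32882 and 32209 in TACI short replicates 2 and 3. No pair of replicates agreed within sampling noise. Nothing in the labels says whether the replicates of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

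The introduced gene was examined first. TNFRSF13B (ENSG00000240505, hg38 chromosome 17, 16929816 to 16972118, minus strand; counted over its exons) stood at 30, 15.6 and 15 CPM in the 3 controls. It reached 717, 720 and 765 CPM in the TACI long libraries and 2880, 2710 and 2500 CPM in the TACI short libraries. Its log2 fold change against control was 5.18 ± 0.28 (SE) with the long isoform (adjusted p = 6.68e-06) and 7.06 ± 0.30 with the short isoform (adjusted p = 1.21e-06; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). TACI short cells held 3.68-fold more TNFRSF13B RNA than TACI long cells, at adjusted p = 0.000332 in the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Counts per gene cannot tell the isoforms apart, so isoform and transgene amount differ together in every comparison of the groups. RNA of the ligands was low throughout: TNFSF13, which encodes APRIL, had 0.7 ± 0.245 CPM in controls, 0.613 ± 0.0748 in TACI long and 0.807 ± 0.115 in TACI short (SD, n = 3), and TNFSF13B, which encodes BAFF, stayed at or under 0.102 CPM in each group mean.

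**Figure D1:**
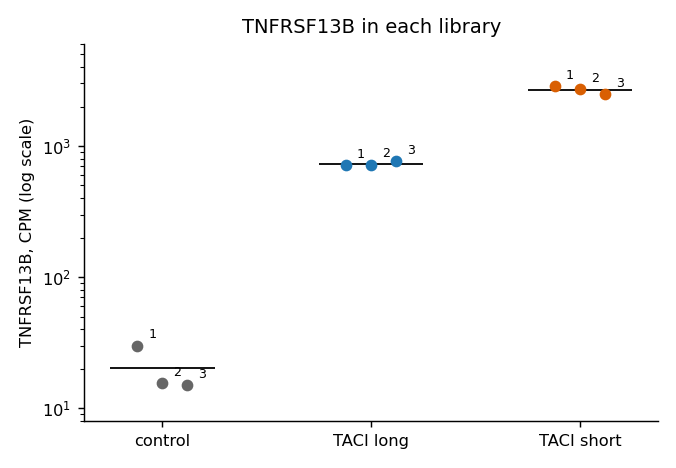
TNFRSF13B in CPM (TMM-scaled, log scale) in each of the 9 libraries, with points numbered by replicate and a line at the group mean. The controls sit between 15 and 30 CPM, TACI long between 717 and 765 and TACI short between 2500 and 2880.

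The first comparison asked how the transcriptome of unstimulated cells given the long isoform differs from that of the parental cells. Cells with TACI long had lower RNA of nearly the whole cholesterol synthesis pathway, of immediate early genes and of the ATF4 response, and higher RNA of endoplasmic reticulum chaperones. In camera, the ATF4 and chaperone lists had adjusted p = 0.0895 and adjusted p = 0.073 with an estimated correlation, while the first 2 stayed under 0.05. HMGCS1, which makes HMG-CoA for the mevalonate pathway, fell from 913 ± 17.2 to 130 ± 0.848 CPM (SD, n = 3), and EGR1, an immediate early transcription factor, from 864 ± 23.7 to 36.4 ± 3.04 CPM. The T-cell and B-cell surface protein CD5 rose 94.9-fold, from 0.439 ± 0.0391 to 41.9 ± 1.9 CPM. Of 16672 genes tested, 4198 were higher and 4320 lower at the 0.05 threshold, and 1520 of these differed by at least 1 on the log2 scale.

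Besides CD5 and TNFRSF13B, the rises of greatest size included those of PRR15L (log2 fold change 4.60 ± 0.15), the gap junction gene GJA3 (3.31 ± 0.07), the taste receptor subunit TAS1R3 (3.16 ± 0.07), SMIM35 (3.10 ± 0.16) and the mitochondrial thiolase ACAA2 (2.72 ± 0.36). The deepest falls were those of MRI1, an enzyme of methionine salvage (-5.15 ± 0.15), the activation marker CD69 (-4.85 ± 0.09), EGR1 (-4.57 ± 0.06), the small GTPase RAB4A (-4.05 ± 0.25), PXDNL (-4.00 ± 0.20), the Fc receptor-like gene FCRL5 (-3.77 ± 0.13) and the surface receptor SLAMF7 (-3.66 ± 0.06). The cytokine-receptor kinase JAK3 belonged to the same set, with 155 counts over the controls and 6 over the TACI long libraries. That made it 24.8-fold lower, with a 95% exact interval of 11.2 to 68.7 from counting error alone. Its fitted log2 fold change moved from -4.56 to -5.43 when TACI long replicate 2 was left out.

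Among 21 tested cholesterol synthesis genes, 20 fell and 1 rose, with a median log2 fold change of -1.42. INSIG1, the sterol-regulated partner of SCAP, fell 6.15-fold and DHCR7, which makes cholesterol from its last precursor, 3.33-fold. The list stood apart from the other genes in limma camera (adjusted p = 2.34e-96), also with an estimated correlation (adjusted p = 0.00191). Of 20 immediate early and heat shock genes, 13 fell and 2 rose. FOS fell 11.7-fold, DUSP2 4.58-fold and IER2 3.57-fold. This list was called as well (camera adjusted p = 6.66e-23, and adjusted p = 0.00587 with an estimated correlation).

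The ATF4 and amino acid response had 16 of 20 genes lower and 2 higher. ATF4 itself fell 2.43-fold, CEBPB 2.76-fold, the mTORC1 inhibitor gene DDIT4 2.49-fold and SESN2 2.48-fold. In the unfolded protein response, 16 of 18 genes rose and 1 fell. The chaperone HSPA5 went from 1097 ± 19.4 to 1834 ± 29.9 CPM (SD, n = 3), HSP90B1 rose 1.57-fold and the disulfide isomerase PDIA6 1.56-fold. Camera gave adjusted p = 1.56e-12 for the ATF4 list and adjusted p = 1.74e-11 for the unfolded protein response, but adjusted p = 0.0895 and adjusted p = 0.073 with an estimated correlation.

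NF-kB targets, which CD40-type and TACI-type receptors can induce, had 15 of 32 tested genes lower and 5 higher, or 16 and 5 adjusted over the list alone. TNF fell 4.26-fold, the lymph-node homing receptor CCR7 9.39-fold, the survival gene BCL2A1 2.38-fold and NFKB1 1.53-fold. The median log2 fold change of the list was only -0.08, and 12 of its genes were not called. The list reached adjusted p = 0.0273 in camera, adjusted p = 0.123 with an estimated correlation, and adjusted p = 0.0627 when only genes at 1 CPM or more in 3 libraries were tested. Of 13 MHC class II genes, 7 fell, with HLA-DMB 2.41-fold and HLA-DQA1 1.74-fold lower, at camera adjusted p = 0.00447 and adjusted p = 0.761 with an estimated correlation. Glycolysis had 13 of 20 genes lower and none higher, 14 adjusted over the list alone, among them ALDOC (4.83-fold) and ENO1 (1.42-fold). Camera gave it adjusted p = 2.64e-05, and adjusted p = 0.513 with an estimated correlation. In the cell cycle list, 14 of 28 genes rose, TOP2A by 1.45-fold, and 2 fell, at camera adjusted p = 0.0428 and adjusted p = 0.834 with an estimated correlation.

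The lists of B-cell and plasma-cell genes moved in both directions. In the plasma cell list, PRDM1, the transcription factor of plasma cell differentiation, rose 2.44-fold, CD27 1.93-fold and the BAFF and APRIL receptor TNFRSF17 2.64-fold, while SLAMF7 fell. In all, 7 of 18 rose and 5 fell (camera adjusted p = 0.728). Of 29 B cell identity and germinal centre genes, 16 rose, with SERPINA9 3.23-fold higher, and 9 fell, with MS4A1 (CD20) 2.36-fold and CD22 2.46-fold lower (camera adjusted p = 0.157). B cell receptor signalling had 6 of 22 genes higher and 11 lower, including the phosphatase gene PTPN6, which fell 2.83-fold (camera adjusted p = 0.135). Mitochondrially encoded genes had 7 of 13 higher, 8 adjusted over the list alone, with MT-CO1 up 1.51-fold (camera adjusted p = 0.0815). All genes with an MT- symbol, of which the list is a part, made up 3.26 to 3.8% of counts against 2.38 to 3.08% in controls. That list passed the threshold when any single control or TACI long library was left out, with adjusted p between 4.85e-06 and 0.0137. It had adjusted p = 0.834 with an estimated correlation, and 3 of 13 genes higher at camera adjusted p = 0.318 without TACI short replicates 2 and 3, or 4 at adjusted p = 0.282 without genes that follow the level of transcripts shared by these. MT-ND4L rose by 0.29 on the log2 scale, but not past the threshold without TACI short replicate 3 (adjusted p = 0.0606).

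Camera called no other list in this comparison, while fry, which does not set members against the other genes, called 8 lists that camera did not (adjusted p from 9.61e-05 for T and NK cell markers to 0.0451 for MHC class I presentation). Members higher and lower were 3 and 4 of 11 TACI ligands and receptors, 6 and 5 of 15 MHC class I presentation genes, 11 and 7 of 34 interferon-stimulated genes (12 and 7 adjusted over the list alone) and 7 and 3 of 19 Toll-like receptor pathway genes. They were 12 and 10 of 26 apoptosis regulators, 4 and 2 of 16 chemokine receptor and adhesion genes and 5 and 2 of 13 immunoglobulin genes. Among markers of other cell types, 2 of 5 T and NK cell genes rose, CD5 among them, and 2 fell (2 and 3 of 6 without TACI short replicates 2 and 3, with the median at -0.14 instead of 0.20), none of 8 myeloid genes passed the test, and 1 of 6 epithelial and fibroblast genes rose and 2 fell. CD3E, a T-cell receptor subunit, rose by 0.58 on the log2 scale, but not past the threshold without control replicate 2 or 3 or TACI long replicate 2 or 3 (adjusted p between 0.0993 and 0.17). NKG7, a gene of cytotoxic cells, fell by 0.50, but not past the threshold without control replicate 3 or TACI long replicate 2 or 3 (adjusted p between 0.0603 and 0.0842). TIRAP, a Toll-like receptor adaptor, fell by 3.32 with all libraries and fell by 4.41 without TACI long replicate 1. Camera adjusted p for these 10 lists lay between 0.11 and 0.941. The median, the mean and the camera direction of a list did not share 1 sign for TACI ligands and receptors (median -0.09, mean 0.39, camera higher), plasma cell genes (0.15, 0.02, lower), MHC class I presentation (0.01, -0.05, lower), the Toll-like receptor pathway (0.12, -0.01, higher), apoptosis regulators (0.02, -0.20, lower) and chemokine receptors and adhesion (0.33, -0.04, lower). Adjusted p of the genes named for TACI long was 0.0416 or lower in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

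**Figure D2:**
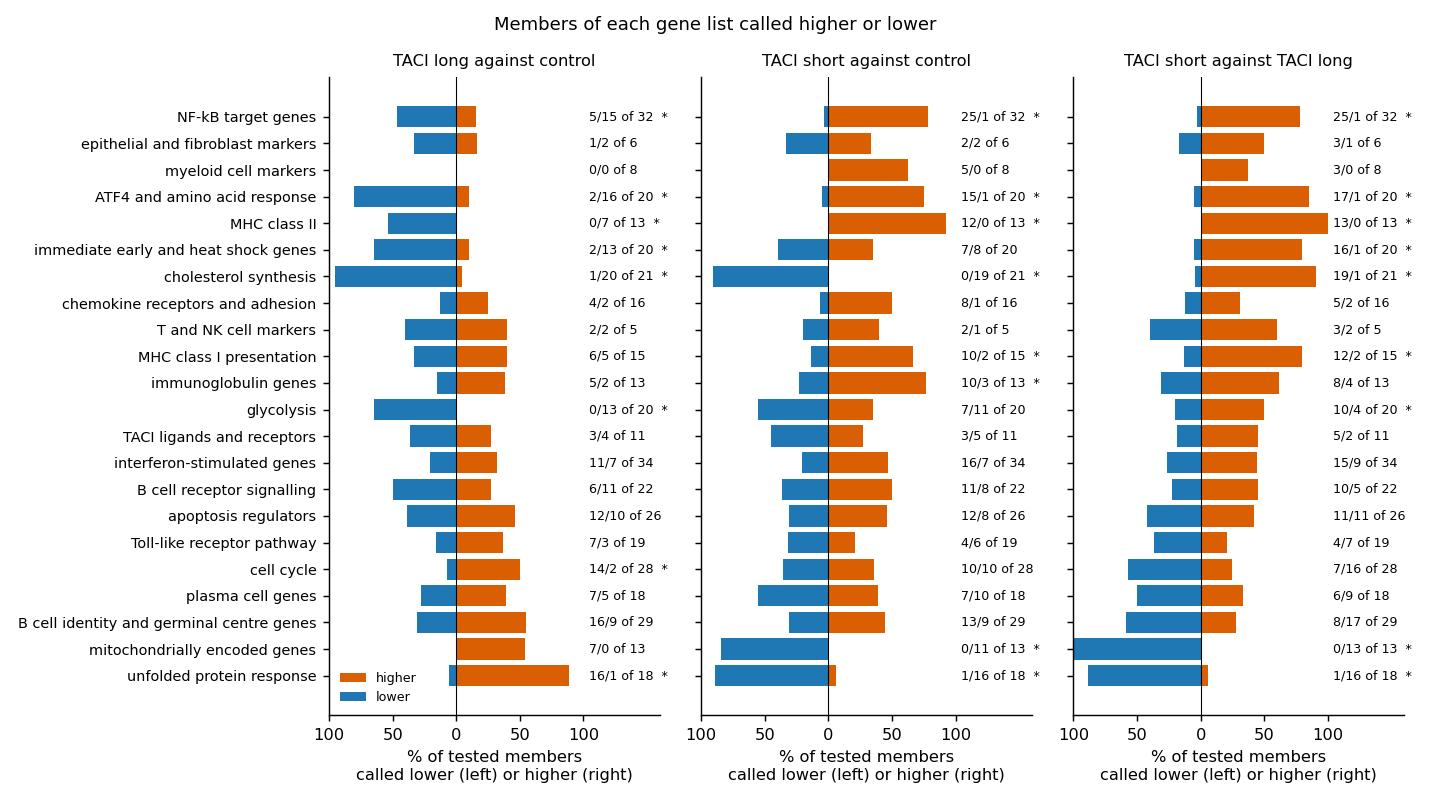
Share of the tested members of each of 22 gene lists that were called lower (blue, to the left) or higher (orange, to the right) in the 3 comparisons, with the number higher, the number lower and the number tested at the right; a star marks a camera adjusted p under 0.05. The unfolded protein response has 16 of 18 members higher in TACI long and 16 of 18 lower in TACI short, each against control.

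The second comparison asked the same of the cells given the short isoform. Cells with TACI short had higher RNA of NF-kB target genes and of both classes of MHC genes, and lower RNA of endoplasmic reticulum chaperones, cholesterol synthesis enzymes and mitochondrially encoded genes. In camera, adjusted p = 0.225 for MHC class II, adjusted p = 0.123 for class I, adjusted p = 0.0703 for chaperones, adjusted p = 0.0895 for cholesterol synthesis and adjusted p = 0.539 for mitochondrial genes with an estimated correlation, and only the NF-kB list of these stayed under 0.05. BIRC3, an apoptosis inhibitor induced by NF-kB, rose from 84.1 ± 1.60 to 664 ± 29 CPM (SD, n = 3), and HSPA5 fell from 1097 ± 19.4 to 474 ± 21.6 CPM. Several genes that were nearly silent in controls were expressed: IL15, a lymphocyte growth factor, rose from 0.221 ± 0.0545 to 14 ± 1.25 CPM. Of the 16672 genes, 5256 were higher and 5179 lower (6320 and 4330 with upper-quartile factors), and 1968 of the higher but 440 of the lower ones differed by at least 1 on the log2 scale. Of 1929 genes that follow the level of transcripts shared by TACI short replicates 2 and 3, 952 were among the higher and 0 among the lower ones. These genes were chosen for rising with a level that is highest in TACI short replicates 2 and 3, which favours this split. Without these replicates, which hold more RNA of myeloid markers than replicate 1, 9146 genes were called instead of 10435, and 8397 of the 10435 kept their call and direction.

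Among the greatest rises were genes with few control counts. The protease gene BACE2 had 1849 counts in TACI short and 7 in controls, a ratio of 244 (95% exact interval 118 to 608). The intestinal disaccharidase gene SI had a ratio of 192 (87.9 to 524), the neuromedin receptor gene NMUR2 of 174 (79.9 to 476) and NCKAP5 of 111 (61.6 to 222). Without control replicate 1 the fitted log2 fold change of BACE2 went from 7.85 to 8.96 and that of NMUR2 from 7.37 to 8.27, and without control replicate 3 that of BACE2 was 7.26. The glycosyltransferase gene B3GNT6 rose by 6.90 ± 0.15 on the log2 scale, IL15 by 5.98 ± 0.19 and the tetraspanin TSPAN11 by 5.76 ± 0.15. The deepest falls were those of GJA3 (-3.19 ± 0.12), SHROOM4 (-2.87 ± 0.16), AGGF1 (-2.69 ± 0.48), MPEG1, which encodes a pore-forming protein of phagocytes (-2.62 ± 0.05), the fatty acid desaturase FADS1 (-2.45 ± 0.13), the serotonin receptor HTR3A (-2.11 ± 0.11), the ciliary gene WDR35 (-2.10 ± 0.15) and the VIP receptor VIPR2 (-2.02 ± 0.11). AGGF1 stood at 0.372 CPM in TACI short replicate 1 and at 1.61 and 1.83 CPM in replicates 2 and 3, against 8.24 ± 0.664 in controls (SD, n = 3).

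In the NF-kB list, 25 of 32 genes rose and SOD2 alone fell, or 26 and 1 adjusted over the list alone. BCL3 rose 8.51-fold, the inhibitor gene NFKBIA 6.26-fold, NFKB2, which encodes the p100 precursor of the non-canonical pathway, 3.68-fold, and CCR7 8.41-fold. The median log2 fold change was 1.77, at camera adjusted p = 9.74e-23 and adjusted p = 0.00113 with an estimated correlation. Without TACI short replicates 2 and 3 the median of the list was 1.29. The TACI ligand and receptor list had 3 of 11 genes higher and 5 lower (camera adjusted p = 0.941). TRAF3, a brake on non-canonical NF-kB signalling, rose 1.69-fold and the adaptor gene MYD88 fell 1.66-fold.

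Of 13 MHC class II genes, 12 rose and none fell, with HLA-DQA1 5.10-fold and HLA-DRB1 1.73-fold higher. In MHC class I presentation, 10 of 15 genes rose and 2 fell, and HLA-B rose 3.55-fold and the peptide transporter TAP1 1.76-fold. Camera gave adjusted p = 3.96e-10 and adjusted p = 3.07e-06 for these lists, and adjusted p = 0.225 and adjusted p = 0.123 with an estimated correlation. Immunoglobulin genes had 10 of 13 higher and 3 lower. IGHM rose 1.84-fold and IGHD fell 3.89-fold (camera adjusted p = 0.00447, and adjusted p = 0.493 with an estimated correlation). HLA and immunoglobulin genes are polymorphic or share sequence with close relatives, so their counts are uncertain.

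The unfolded protein response moved against its direction in TACI long: 16 of 18 genes fell and 1 rose. CALR fell 2.02-fold and the chaperone cofactor DNAJB11 1.98-fold, and MANF went from 119 ± 4.84 to 59.4 ± 4 CPM (SD, n = 3). The ATF4 and amino acid response had 15 of 20 genes higher and 1 lower, with DDIT4 up 3.76-fold, the serine synthesis gene PSAT1 1.85-fold and the asparagine synthetase gene ASNS 1.74-fold. Camera adjusted p was 4.12e-11 for the unfolded protein response and 9.47e-08 for the ATF4 list. With an estimated correlation, adjusted p = 0.0703 and adjusted p = 0.165. Cholesterol synthesis again moved down, with 19 of 21 genes lower and none higher. HMGCS1 fell 1.76-fold (camera adjusted p = 2.23e-12, and adjusted p = 0.0895 with an estimated correlation).

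Mitochondrially encoded genes had 11 of 13 lower and none higher, 12 adjusted over the list alone. MT-ND2 fell 2.67-fold and MT-CO3 1.92-fold. All genes with an MT- symbol, of which the list is a part, made up 1.77 to 2.07% of counts in TACI short. For the list, camera adjusted p was 2.92e-06 and, with an estimated correlation, adjusted p = 0.539. In the plasma cell list, PRDM1 rose 2.18-fold, while SLAMF7 fell 2.22-fold and MZB1, a chaperone of immunoglobulin assembly, 1.51-fold. Overall 7 of 18 rose and 10 fell (camera adjusted p = 0.205). B cell identity genes were split 13 higher to 9 lower of 29, with the follicular homing receptor CXCR5 up 2.42-fold and MS4A1 down 2.27-fold (camera adjusted p = 0.784).

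Markers of other cell types separated the TACI short libraries from each other. Of 8 myeloid markers tested, 5 rose and none fell (camera adjusted p = 0.103), with a median log2 fold change of 1.73. CSF1R, the receptor for macrophage colony-stimulating factor, stood at 19.7 CPM in TACI short replicate 1 and at 52.8 and 53.5 CPM in replicates 2 and 3, and at 7.14 ± 2.73 in controls (SD, n = 3). TYROBP, an adaptor of myeloid cells, had 0.940, 11.4 and 10.1 CPM in these replicates and between 0.904 and 2.51 CPM in controls. CST3 alone was even, at 38.0, 40.4 and 41.0 CPM, and 1.65-fold over control. Without replicates 2 and 3 the median of the myeloid list was -0.13, 1 member passed the test and CSF1R did not (log2 fold change 1.46, adjusted p = 0.0817, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). CD14, a monocyte surface receptor, rose by 1.08 on the log2 scale with all libraries. It did not pass without control replicate 1, 2 or 3 or TACI short replicate 2 or 3 (adjusted p between 0.0527 and 0.107), and stood at -0.17 without replicates 2 and 3 together (adjusted p = 0.78). LYZ, which encodes lysozyme, rose by 1.39, but not past the threshold without control replicate 1 or 3 or TACI short replicate 2 or 3 (adjusted p between 0.0546 and 0.0806), and stood at 0.14 without both of the latter (adjusted p = 0.793). The collagen gene COL1A1 rose by 1.83, but not past the threshold without control replicate 1 or 2 or TACI short replicate 3 (adjusted p between 0.0528 and 0.0621), and stood at 0.55 without TACI short replicates 2 and 3 (adjusted p = 0.112). The matrix gene LUM rose by 0.90 and DCN fell by 0.45, with adjusted p between 0.0522 and 0.126 without control replicate 1 or 3 or TACI short replicate 2, and for LUM 0.0536 without TACI short replicate 3. Without replicates 2 and 3 they stood at 0.72 (adjusted p = 0.248) and -0.33 (adjusted p = 0.192). CD4 rose by 0.99 and stood at 0.22 without replicates 2 and 3 (adjusted p = 0.585). The myeloid list passed the threshold without TACI short replicate 1 (adjusted p = 0.0123). Chemokine receptor and adhesion genes had 8 of 16 higher, CXCR4 by 2.68-fold, and 1 lower (camera adjusted p = 0.0666). Without TACI short replicate 1 this list passed too (adjusted p = 0.000444), and without replicates 2 and 3 its counts were 4 higher and 3 lower of 17.

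**Figure D3:**
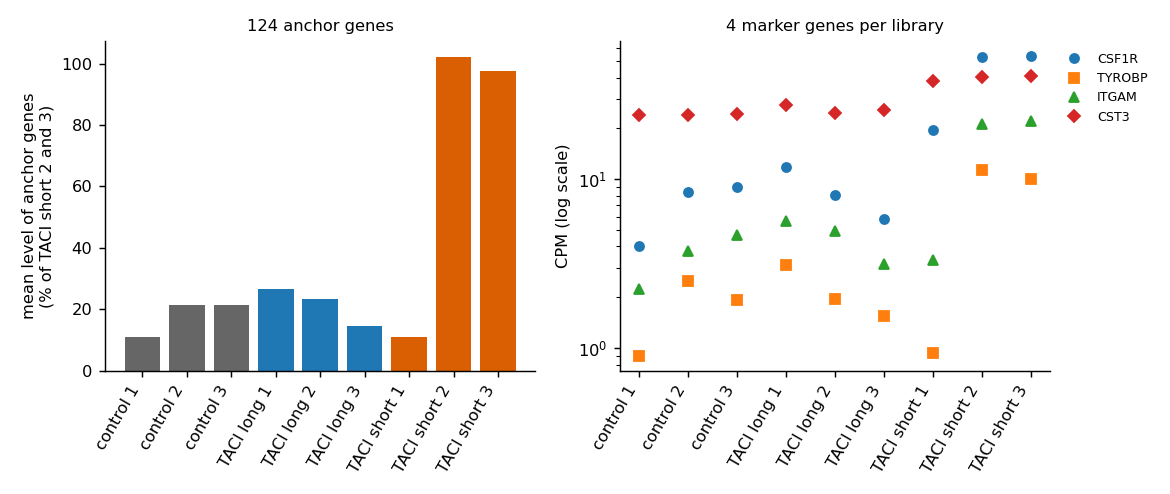
Left, mean level of 124 genes that were at least 6-fold higher in TACI short replicates 2 and 3 than in replicate 1, as a percentage of their mean in replicates 2 and 3, per library. Right, CPM on a log scale of 4 myeloid markers per library: CSF1R, TYROBP and ITGAM are highest in TACI short replicates 2 and 3, while CST3 is alike in the 3 TACI short libraries.

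Camera did not call the remaining lists in TACI short, while fry called 10 lists that camera did not (adjusted p from 0.000296 for plasma cell genes to 0.0448 for B cell identity genes). Members higher and lower were 11 and 8 of 22 B cell receptor signalling genes, 16 and 7 of 34 interferon-stimulated genes, 4 and 6 of 19 Toll-like receptor pathway genes and 10 and 10 of 28 cell cycle genes (11 and 10 adjusted over the list alone). They were 12 and 8 of 26 apoptosis regulators (13 and 10 adjusted over the list alone), 7 and 11 of 20 glycolysis genes, 7 and 8 of 20 immediate early and heat shock genes, 2 and 1 of 5 T and NK cell markers and 2 and 2 of 6 epithelial and fibroblast markers. Without TACI short replicates 2 and 3, higher and lower were 11 and 11 interferon-stimulated genes, with the median log2 fold change at 0.02 instead of 0.34. They were 0 and 2 epithelial and fibroblast markers (median -0.37 instead of 1.05), 1 and 3 T and NK cell markers of 6 tested (-0.33 instead of 0.08) and 6 and 8 immediate early and heat shock genes (-0.17 instead of 0.10). Camera adjusted p for these 9 lists lay between 0.11 and 0.995. The median, the mean and the camera direction did not share 1 sign for TACI ligands and receptors (median -0.09, mean 0.54, camera higher), plasma cell genes (-0.26, 0.05, lower), B cell identity genes (0.09, 0.004, lower), the Toll-like receptor pathway (-0.02, 0.12, lower), the cell cycle (0.04, 0.01, lower), glycolysis (-0.20, 0.20, higher), immediate early genes (0.10, 0.15, lower) and epithelial and fibroblast markers (1.05, 0.75, lower). Adjusted p of the genes named for TACI short was 0.0292 or lower in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

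**Figure D4:**
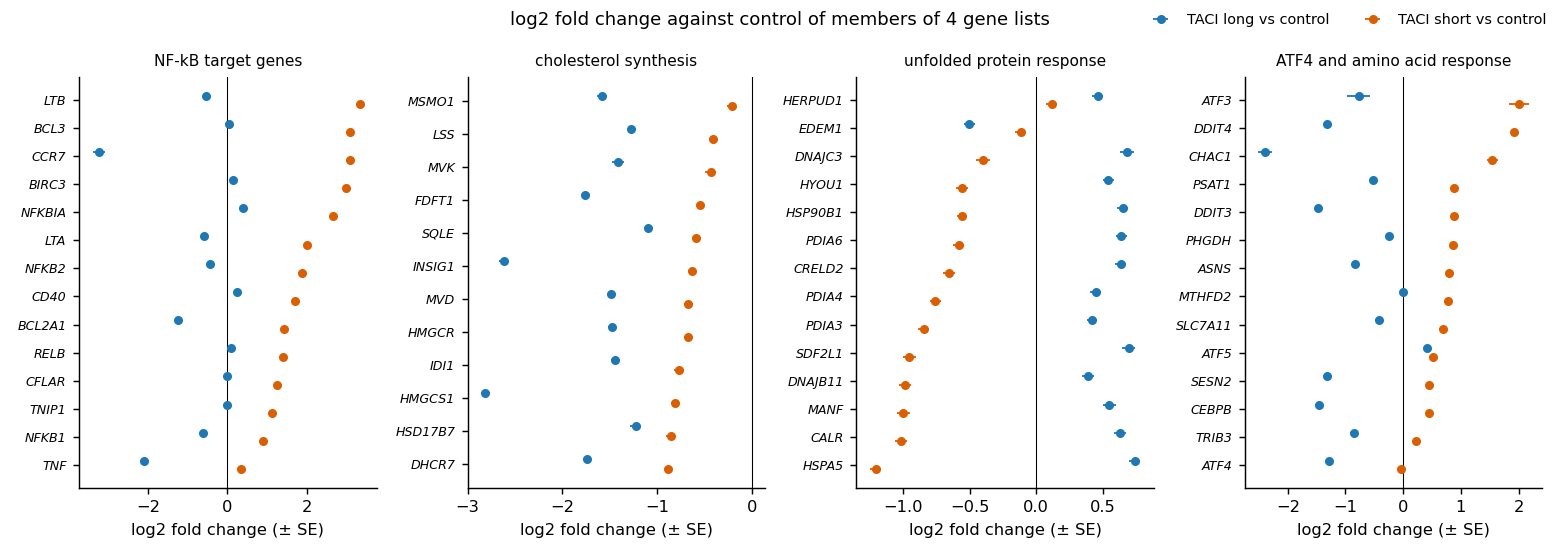
Log2 fold change against control, with its approximate standard error, of up to 14 members of 4 lists (taken from those with the smallest adjusted p in either line, not all of which are drawn) in TACI long (blue) and TACI short (orange). HSPA5 lies at 0.74 in TACI long and at -1.21 in TACI short, HMGCS1 at -2.81 and -0.82.

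The third comparison set the cells given each isoform against each other. TACI short cells had more RNA of NF-kB targets, MHC class II genes and the ATF4 response than TACI long cells, and less of endoplasmic reticulum chaperones and mitochondrially encoded genes. In camera, adjusted p = 0.189 for MHC class II, adjusted p = 0.0895 for the ATF4 list and adjusted p = 0.493 for mitochondrial genes with an estimated correlation, and the other 2 lists stayed under 0.05. NFKB2 stood at 276 ± 17.3 CPM in TACI short and 55.5 ± 1.08 in TACI long (SD, n = 3), CALR at 623 ± 36.3 and 1952 ± 35.3 CPM. CD70, the ligand of CD27, was 84.5-fold higher in TACI short, and GJA3 was 90.5-fold lower. Of the 16672 genes, 5870 were higher and 5604 lower in TACI short (6820 and 4770 with upper-quartile factors). Among them were 957 higher and 4 lower genes that follow the shared level, a split that their choice favours. Without TACI short replicates 2 and 3, 10462 genes were called instead of 11474, of which 9694 were among the 11474 with the same direction.

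The genes that stood highest in TACI short relative to TACI long included several with few TACI long counts. NMUR2 had 1132 counts in TACI short and 1 in TACI long, a ratio of 1010 (95% exact interval 180 to 39800). The ratio was 338 (155 to 923) for JAK3, 179 (97 to 373) for IL15 and 111 (60 to 231) for SI. BACE2 stood at 12.9 ± 0.598 CPM against 0.121 ± 0.109 (SD, n = 3). B3GNT6 was higher by 7.14 ± 0.15 on the log2 scale and CCR7 by 6.30 ± 0.14. Leaving out TACI long replicate 1 moved the fitted log2 fold change of NMUR2 from 9.54 to 11.48 and of BACE2 from 6.73 to 7.71, and leaving out TACI long replicate 2 moved JAK3 from 8.34 to 9.21 and SI from 6.75 to 7.79. Lower in TACI short were, besides GJA3 (-6.50 ± 0.10), SMIM35 (-3.62 ± 0.17), SHROOM4 (-3.41 ± 0.16), PRR15L (-3.16 ± 0.13), ZNF696 (-3.05 ± 0.22), the desaturase SCD5 (-3.05 ± 0.11), ACAA2 (-3.04 ± 0.37) and VIPR2 (-2.70 ± 0.11). Without TACI short replicates 2 and 3 the value of ZNF696 was -3.86 and that of ACAA2 -4.40.

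Of 32 NF-kB targets, 25 were higher in TACI short and 1 lower, or 26 and 1 adjusted over the list alone. BIRC3 was 7.22-fold, NFKB2 4.98-fold and NFKBIA 4.78-fold higher (camera adjusted p = 1.8e-20, and adjusted p = 0.00113 with an estimated correlation). In the unfolded protein response 16 of 18 were lower and 1 higher, with HSPA5 3.87-fold and SDF2L1 3.14-fold lower (camera adjusted p = 1.65e-15, and adjusted p = 0.0383 with an estimated correlation). The ATF4 list had 17 of 20 higher and 1 lower, with DDIT4 9.37-fold, the pro-apoptotic factor DDIT3 5.12-fold and ASNS 3.09-fold higher. MHC class II had 13 of 13 higher, HLA-DQA1 by 8.85-fold, and MHC class I presentation 12 of 15 higher and 2 lower, HLA-E being 2.69-fold higher. Camera adjusted p was 3.02e-13, 1.35e-11 and 7.46e-06 for these 3 lists, and adjusted p = 0.0895, adjusted p = 0.189 and adjusted p = 0.145 with an estimated correlation.

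Immediate early genes were higher in TACI short in 16 of 20 cases and lower in 1 (17 and 1 adjusted over the list alone). EGR1 was 11.8-fold, JUNB 3.10-fold and IER2 2.90-fold higher. Of 21 cholesterol synthesis genes, 19 were higher and 1 lower, with HMGCS1 3.99-fold and INSIG1 3.97-fold higher. Mitochondrially encoded genes were lower in 13 of 13 cases, MT-ND2 by 3.54-fold. Camera adjusted p for these lists was 1.87e-07, 4.02e-13 and 1.68e-07, and adjusted p = 0.0703, adjusted p = 0.105 and adjusted p = 0.493 with an estimated correlation. In glycolysis 10 of 20 genes were higher and 4 lower, with ALDOC 15.5-fold and PDK1 3.56-fold higher. Its camera adjusted p of 0.0303 became 0.814 with an estimated correlation. It also lay above the threshold without any single control or TACI long library, or without TACI short replicate 3, at adjusted p between 0.053 and 0.0998.

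Camera called no other list between the isoforms, while fry called 12 lists that camera did not (adjusted p from 0.000121 for B cell receptor signalling to 0.0434 for epithelial and fibroblast markers). In the cell cycle list, 16 of 28 genes were lower in TACI short, among them the replication genes RRM2 (1.79-fold), MCM3 (1.44-fold) and MCM5 (1.41-fold), and 7 were higher (camera adjusted p = 0.106, and adjusted p = 0.034 without TACI short replicate 1). In the apoptosis list, the p53-inducible genes BBC3 and PMAIP1 were 6.28-fold and 4.47-fold higher, within 11 higher and 11 lower of 26. The B cell identity list had 8 of 29 higher, with LMO2 5.25-fold up, and 17 lower, with SERPINA9 2.56-fold down (camera adjusted p = 0.0815). This list passed without TACI short replicate 1 (adjusted p = 0.031) or TACI long replicate 1 (adjusted p = 0.0477). In the plasma cell list 6 of 18 were higher, SLAMF7 by 5.71-fold, and 9 lower, TNFRSF17 by 4.52-fold. Higher and lower were 5 and 2 of 11 TACI ligands and receptors (5 and 3 adjusted over the list alone), 10 and 5 of 22 B cell receptor signalling genes (12 and 7 adjusted over the list alone), 15 and 9 of 34 interferon-stimulated genes (12 and 12 without TACI short replicates 2 and 3) and 4 and 7 of 19 Toll-like receptor pathway genes. They were 5 and 2 of 16 chemokine receptor and adhesion genes (CD69 being 22.5-fold higher), 8 and 4 of 13 immunoglobulin genes, 3 and 2 of 5 T and NK cell markers, 3 and 0 of 8 myeloid markers and 3 and 1 of 6 epithelial and fibroblast markers. Without TACI short replicates 2 and 3 these were 4 and 5 chemokine receptor and adhesion genes (median log2 fold change -0.09 instead of 0.59), 2 and 2 T and NK cell markers (-0.05 instead of 0.58), 1 and 1 myeloid markers (-0.21 instead of 1.54) and 2 and 1 epithelial and fibroblast markers (0.04 instead of 1.75). The chemokine receptor list passed without TACI short replicate 1 (adjusted p = 0.00193), the library with the fewest myeloid transcripts of the 3. COL1A1 was higher by 1.78 on the log2 scale, but not past the threshold without TACI long replicate 3 (adjusted p = 0.0615) or TACI short replicate 3 (adjusted p = 0.0531), and it stood at 0.50 without TACI short replicates 2 and 3 together (adjusted p = 0.14). Camera adjusted p for these 13 lists lay between 0.0815 and 0.792. The median, the mean and the camera direction did not share 1 sign for plasma cell genes (median -0.17, mean 0.03, camera lower), the Toll-like receptor pathway (-0.08, 0.13, lower), apoptosis regulators (-0.03, 0.37, higher) and T and NK cell markers (0.58, -0.24, lower). Adjusted p of the genes named between the isoforms was 0.017 or lower in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

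The last comparison asked how far the same genes differed from control in the cells given either isoform. CD5 and the microtubule gene MAP2 rose in both lines, by 6.57 and 2.36 on the log2 scale in TACI long and by 4.20 and 4.43 in TACI short. MPEG1 fell 9.88-fold in TACI long and 6.14-fold in TACI short, FADS1 10.6-fold and 5.46-fold. In the opposite way, JAK3, CCR7 and the transporter ABCA8 fell in TACI long and rose in TACI short, and GJA3 rose in TACI long and fell in TACI short. Altogether 3408 genes were called in both lines with the same direction (1617 higher and 1791 lower) and 2580 with opposite directions. Independent lists of these sizes would share 2665 genes in the same direction and 2666 in opposite directions. In 20 simulations of unchanged groups set against shared controls, at most 3 genes were called in both with the same direction. The simulations hold no changed genes, so their count does not show how many calls in the data come from the shared controls. The covariance of the log2 fold changes over genes was 0.117, against 0.0369 in the simulations, and their correlation was 0.176 against 0.502. The 3 controls cannot be divided into parts of at least 2 libraries for each comparison, so part of the overlap may come from the shared controls.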

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

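Every weighing of explanations here was chosen after the result was seen, while the 10 splits of the libraries in each comparison were planned.

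Genes and lists called in opposite directions against control in TACI long and TACI short differed as follows in the direct test of TACI short against TACI long. JAK3 (8.34), CCR7 (6.30) and ABCA8 (6.12 on the log2 scale) were higher in TACI short, and GJA3 was lower (-6.50), each by the edgeR quasi-likelihood test. Against control, the median log2 fold change of NF-kB target genes was -0.08 in TACI long and 1.77 in TACI short. It was 0.55 and -0.57 for the unfolded protein response, -0.47 and 0.60 for the ATF4 list and -0.12 and 0.73 for MHC class II. Between the lines, the median log2 difference was 2.08 for NF-kB target genes, -1.21 for the unfolded protein response, 1.18 for the ATF4 and amino acid response and 0.93 for MHC class II. With an estimated correlation limma camera gave adjusted p = 0.00113, adjusted p = 0.0383, adjusted p = 0.0895 and adjusted p = 0.189 for these differences. Against control, in the same order, camera with an estimated correlation gave adjusted p = 0.123, adjusted p = 0.073, adjusted p = 0.0895 and adjusted p = 0.761 in TACI long. In TACI short it gave adjusted p = 0.00113, adjusted p = 0.0703, adjusted p = 0.165 and adjusted p = 0.225. Camera calls of opposite directions in both lines therefore rest on the preset correlation. Fry, which does not set members against the other genes, called these lists in the same opposite directions. Against control, it called 16 of 22 lists in TACI long and 18 of 22 in TACI short. In these comparisons 51.1 and 62.6% of all genes were called, so most lists hold changed genes. Fry therefore cannot show that these lists moved apart from the other genes, and its calls do not replace those of camera. In the same order, fry gave adjusted p = 6.94e-06, adjusted p = 2.46e-06, adjusted p = 5.3e-06 and adjusted p = 0.00132 in TACI long. In TACI short fry gave adjusted p = 1.64e-09, adjusted p = 3.84e-07, adjusted p = 7.14e-06 and adjusted p = 1.52e-05.

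A response that follows the amount of TNFRSF13B mRNA in 1 direction would move genes alike in both lines, since TNFRSF13B was above control in both, yet over all 22 lists 111 members were called in opposite directions and 116 in the same one, with 29.7 false calls expected. Over all genes these numbers were 2580, 3408 and 948, which argues against it as the only cause of the calls. The false calls expected cover only the spread between these libraries, which may be technical. Independent lists of called genes would share 2666 in opposite directions, so unrelated differences between the lines could give as many. The test was first run on the 4 lists (47 opposite, 7 the same), which were picked for their opposite directions. Foreign transcripts in TACI short replicates 2 and 3 are argued against by the 4 of 4 lists that kept their direction and camera call without these libraries. A response that turns with the amount of receptor stays open. Differences between the lines apart from the isoform cannot be told apart from an isoform effect, because there is 1 group of libraries per isoform.

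Myeloid markers stood higher in TACI short replicates 2 and 3 than in replicate 1, although the cells were sorted. If the short isoform raised them, replicate 1 should show it, but the median log2 fold change of the fixed list was -0.131 in replicate 1 alone against 1.73 with all 3. A single library excludes nothing, and CSF1R (19.7 CPM against 4 to 8.98 in controls) and CST3 (38 against 23.9 to 24.3) were higher in replicate 1 too, so this stays open. A foreign profile present at a different level in each library may account for part of it. Of 124 genes picked in the TACI short libraries alone, 100% were lowest in control replicate 1 among controls and 100% in TACI long replicate 3. This common order shows that the 124 genes vary together. It cannot tell foreign RNA from RNA of the BJAB cells themselves. Among the markers the most abundant were CSF1R at 53.5 CPM and CST3 at 41 CPM, and LYZ reached 2.19 CPM, while of the 124 genes SPP1 stood at 611 and 595 CPM in replicates 2 and 3 and 59.5 in replicate 1, and IL1B at 199, 191 and 20.6 (chosen after their values were seen).

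TNFRSF13B was higher in control replicate 1 (30 CPM) than in controls 2 and 3 (15.6 and 15 CPM), an excess of 0.544% of the TACI short level. A small share of TACI short material or reads in control replicate 1 may account for it: 23 other genes at least 20-fold higher in TACI short than in controls 2 and 3 had an excess of 0.583% ± 0.147 (SE) there. The excess in these genes was 3.39 CPM, and 15 of 23 were highest in control replicate 1. Its SE covers counting error and the difference between controls 2 and 3, not a departure of control replicate 1 from them. Over all genes, control replicate 1 differed more from them (chi-square per degree of freedom 6.76 and 7.02) than they did from each other (2.75). The excess therefore cannot decide against higher expression of TNFRSF13B alone. Choosing genes low in controls 2 and 3 favours an excess in control 1, and an earlier selection against all 3 controls gave 0.481% ± 0.142 (2.76 CPM, 14 of 23 genes). No biological explanation other than expression in that library was tested.

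The real split called 8518 genes for TACI long against control, 10435 for TACI short against control and 11474 between the isoforms, and 1 of the 10 splits in each comparison, the real one, reached that number. The highest of the other splits called 0 genes in each. Because 10 splits are too few for a share under 0.05, nothing more can be said from them.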

How the results depend on the processing

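Leaving out TACI short replicates 2 and 3 and leaving out genes that follow the level of transcripts shared by these libraries (2 definitions) were chosen after the data were seen, and the other alternatives before. Counts of called genes stayed within 1.5 times under both other scalings, DESeq2, limma-voom, both other filters, the groups compared alone and each library left out (7308 to 9142, 9270 to 11588 and 10000 to 12661 genes in the 3 comparisons, and 2769 to 3655 for the same direction in both lines). They moved with a minimum size, by construction: with an absolute log2 fold change of at least 1 they were 1520, 2408, 3330 and 347. With glmTreat against a fold of 1.2 they moved to 4154 and 6177 against control, while the 7874 between the isoforms stayed within 1.5 times. TNFRSF13B kept its direction and call throughout, at 5.01 to 5.59, 6.87 to 7.45 and 1.82 to 1.97. With the replicate block, 8620, 10501, 11495 and 3489 genes were called. In TACI long it ended the calls of CD3E (adjusted p = 0.0547 by edgeR) and MT-ND4L (adjusted p = 0.09), and no other named call changed. Of 9 same-number pairs 4 correlated above 0.1, and 4 of 9 libraries correlated best with their own number. All 3 pairs of control and TACI short did (0.434, 0.213 and 0.177), though control 3 correlated more with TACI short 2 (0.232). Same-number pairs with TACI long ran from -0.272 to 0.113. Among unlike numbers, TACI long 3 correlated with TACI short 1 at 0.346 and with control 1 at 0.209. Control 1, TACI long 3 and TACI short 1 each had the lowest shared level of their group (10.8, 14.5 and 10.8%). The correlations therefore cannot tell a pairing by number from that level, and the labels give no meaning to the numbers.

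Of 307 named gene results, 294 kept direction and call under every alternative that gave a value. Of 6072 pairs of gene and alternative with a value, 62 lost the call, and 68 gave no value. Most of the 68 were genes removed for following the shared level. With the first definition of these, 255 of the 307 results had a value, and all kept direction and call. The 294 therefore include results for removed genes. CD14 in TACI short against control reversed without TACI short replicates 2 and 3 (-0.167, adjusted p = 0.78 by edgeR; the cause was not tested), where 10 more results lost their call. All genes that lost a call were markers of other cell types or MT-ND4L. Without those libraries TACI short is 1 library, assumed to vary like the others; 9382, 9146 and 10462 genes were called. Without the genes that follow the shared level these were 8872, 9942 and 10922, and with the first definition 8319, 9439 and 10231.

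Of 25 called lists, 5 stayed called with an estimated correlation and 23 to 25 under every other alternative tried on lists. The 23 came with the first definition of genes that follow the shared level, where some lists had too few genes left to be tested. Fry called these 25 and 30 more of the 66 list results. Glycolysis between the isoforms was lost without a filter (adjusted p = 0.0947 in camera). Without a filter, lists newly called were B cell identity (TACI long, and between the isoforms), mitochondrial genes (TACI long), Toll-like receptor pathway and myeloid markers (TACI short) and cell cycle (between the isoforms). B cell receptor signalling between the isoforms passed with upper-quartile factors (adjusted p = 0.0469 in camera) and without TACI short replicates 2 and 3 (adjusted p = 0.0288). Without genes that follow the shared level, camera newly called chemokine receptors and adhesion in TACI short (adjusted p = 0.0439) and between the isoforms (adjusted p = 0.0384), and B cell receptor signalling between the isoforms (adjusted p = 0.0439). With the first definition it newly called the chemokine receptor list in both (adjusted p = 0.0137 and adjusted p = 0.012) and interferon-stimulated genes in TACI short (adjusted p = 0.012). Upper-quartile factors moved the median of all genes to 0.107 and 0.135 in the comparisons with TACI short, from 0.026 and 0.046.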

Other observations

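The test of a shared profile was chosen after the result was seen, and the values below belong to no planned comparison.

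The 124 genes picked in the TACI short libraries had a mean level, relative to TACI short replicates 2 and 3, of 10.8% in TACI short replicate 1. In control replicates 1, 2 and 3 it was 10.8, 21.5 and 21.4%, and in TACI long replicates 1, 2 and 3 it was 26.6, 23.3 and 14.5%. The intermediate filament gene VIM, chosen after its values were seen, stood at 3.3 CPM in TACI short replicate 1 and at 21.1 and 23.2 CPM in replicates 2 and 3.

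Olfactory receptor genes, 376 in number and silent in most tissues, had 154 to 193 counts per megabase of exon in the control and TACI long libraries. They had 265 in TACI short replicate 1, 696 in replicate 2 and 552 in replicate 3. Of genes without a count in the other 7 libraries, 5327 had a count in TACI short replicate 2 and 4698 in replicate 3.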
